A study of Homo sapiens with 10 samples.

How the data were processed

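The series measured ribosome-protected RNA fragments (footprints) and total RNA in KOPT-K1, a human T-cell acute lymphoblastic leukaemia (T-ALL) line. Cells received DMSO or 25 nM silvestrol, an inhibitor of the translation initiation helicase eIF4A, for 45 minutes. The labels give 2 footprint libraries and 3 total RNA libraries per treatment, 10 libraries in all. They do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Groups and replicate numbers were taken from the sample titles.

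The authors deposited 1 file per library with RPKM values for 55889 Ensembl gene IDs, per the file headers. STAR and the genome build hg19 are named in the submitters' processing notes, without a version or a role. The counting tool, the annotation release, the gene lengths, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Genes with near-identical copies, such as ribosomal protein genes with their pseudogenes, and genes that overlap an antisense gene are therefore uncertain. A table of gene names matched 49395 of the IDs, GENCODE release 29 named 267 more, and 6227 stayed without a name and are given by ID. GENCODE release 29, which is on another build, was used only for names, gene types, exon lengths and the sequences of 5' untranslated regions (UTRs) and coding regions. Its coordinates served only to derive these lengths and the bounds of these regions, and genes were matched to the deposited values by ID.

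The deposited RPKM values carry no depth, so it was estimated. Low values of a gene were whole multiples of a step, the value of 1 read, and the step multiplied by the exon length in GENCODE release 29 gave each library's total. The estimates were 2.27 and 1.66 M reads for the DMSO footprint libraries and 2.38 and 2.04 M for the silvestrol footprint libraries. The DMSO RNA libraries came to 167.4, 216.8 and 160.5 M and the silvestrol RNA libraries to 126.6, 178.0 and 151.1 M. With the same lengths, reads summed over genes came to 118.3% to 119.8% of these RNA totals, so the RNA totals and the lengths conflict and the totals are rough. Among genes with 1 annotated transcript and under 10.5 reads, between 90.29% and 92.94% of values lay within 0.05 of a whole read. Lengths that differ from the authors' would move these totals, so they are called estimated reads, and no count model serves as a main test. The median SD between replicates on the log2 scale was 0.18 in DMSO and 0.19 in silvestrol footprints, against 0.04 and 0.05 in RNA. Values that use footprints are thus less precise than RNA values, and the parts of depth and replicate number in this were not tested.

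Values were transformed to log2(RPKM + 0.5), a scale that understates changes of low genes. Genes with a mean RPKM of at least 1 over the RNA libraries and at least 1 over the footprint libraries were tested, 10297 genes of which 9017 were protein-coding. Libraries were taken as deposited. The analysis used R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend and robust) and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Translational efficiency was tested as the interaction of assay and treatment in 1 fit of 4 group means over the 10 libraries, which gives both assays 1 estimate of the spread. The footprint comparison used the 4 footprint libraries alone and the RNA comparison the 6 RNA libraries alone. All tests were two-sided.

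The comparisons, the weights per assay and a list test were run on simulated data at the estimated depths, 10052 genes of which 200 were changed. Spread beyond counting was set by hand for each assay, alike for all genes, and genes were drawn independently. Shifts shared by many genes of a library were therefore absent, and real libraries can give more false calls. For translational efficiency the fit recovered 41.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 95.5% of those changed 4-fold, but made 238 false calls, 62.5% of all calls. That share of false calls depends on the number of changed genes and the spread put in, so it is not the error rate of the real calls. With nothing changed the fit still made 106 calls and gave 1718 genes an unadjusted p under 0.05. With weights estimated per assay, the shares were 11.9%, 61.2% and 95.5% with 28 false calls, and 11 calls with nothing changed. The footprint comparison recovered 4.48%, 32.8% and 81.8% at the same folds with 17 false calls, and made 11 calls with nothing changed. The RNA comparison recovered 97.0%, 100% and 98.5% of genes changed 1.2-fold, 1.5-fold and 2-fold with 9 false calls, and made 2 calls with nothing changed. In the list test, 30 genes lowered 1.2-fold were found and an unchanged list was not, in genes drawn without correlation.

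The 24 gene lists were fixed before the data were examined, together with the tests, the main alternatives and the rule for named genes. They cover T-ALL oncogenes and transcription factors, the NOTCH pathway, T-cell identity, markers of other cell types, ribosomal proteins and other mRNAs with a 5' terminal oligopyrimidine (TOP) tract, translation initiation factors, aminoacyl-tRNA synthetases, cell cycle, apoptosis, chromatin regulators, PI3K and mTOR signalling, immediate early and short-lived mRNAs, the integrated stress response and chaperones. They also cover nuclear and mitochondrial oxidative phosphorylation genes, mitochondrial ribosomal proteins, the proteasome, glycolysis, cholesterol synthesis, splicing factors, snoRNA host and NMD-sensitive transcripts and replication-dependent histones. The 22 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it. Named genes are the 10 called genes with the largest rise and fall per comparison whose libraries do not overlap between treatments, up to 4 members per list (called members first, otherwise the 2 with the smallest p), and 14 genes fixed by name. The value of 1 gene that this rule names is not reported here. For translational efficiency the largest changes were mostly short non-coding genes with few reads. The 10 protein-coding genes with at least 20 estimated reads and the largest change in each direction were added after the values were seen.

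For 5' UTRs the transcript with the longest coding sequence was used. A run of 4 GGC or CGG repeats and the pattern of 4 runs of at least 2 G separated by 1 to 7 bases (a predicted G-quadruplex) were searched. Medians were compared by permutation tests with 100000 resamples, shares by Fisher's exact test, and relations across genes by Spearman's rho with 10000 permutations in a family of 24 relations, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0. Genes are not independent replicates, so these p-values describe the genes of these libraries. A 5' UTR was found for 8767 of the tested genes. These are the genes meant below by genes with a coding sequence. Genes with a coding sequence but no annotated 5' UTR, such as the mitochondrially encoded mRNAs, are not in that set. Figures were drawn with matplotlib 3.10.9.

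The alternatives tried were other pseudocounts, filters, scalings, thresholds and eBayes settings, a replicate block, leaving out each library, weights per assay, ratios of footprint to RNA libraries of the same number (which the labels do not say are paired), other sets of libraries, an estimated list correlation, and other definitions and backgrounds for 5' UTRs. Chosen after seeing the data were the filter of at least 20 estimated reads, voom on estimated reads, protein-coding genes or genes with a coding sequence alone, a correction of each library for the GC content of coding sequences (lowess with a span of 0.3, within its assay), and a background matched on the longest 5' UTR. The correction for coding GC was run in the genes with a coding sequence. It removed each library's level against its assay's mean together with the GC trend, so it also recentred the libraries. What is called TMM factors below is a simplified form, an unweighted trimmed mean of log2 RPKM ratios to the mean library of an assay. It uses no counts and no weights, unlike the TMM method for counts. No library was left out of the main comparisons.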

Results

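Footprints and total RNA were sequenced from KOPT-K1 cells, a human T-ALL line, treated with DMSO or with silvestrol at 25 nM for 45 minutes. Each treatment had 2 footprint libraries and 3 RNA libraries. The footprint libraries held an estimated 1.66 to 2.38 M reads and the RNA libraries, by a rough estimate, 126.6 to 216.8 M. Between 14491 and 14933 genes had a footprint value above 0, and between 26561 and 28377 an RNA value above 0. Footprint libraries of the same treatment correlated at r = 0.928 (DMSO) and r = 0.921 (silvestrol) across genes. Pairs from different treatments gave 0.919 to 0.931. The median absolute log2 difference was 0.25 and 0.27 in pairs of the same treatment and 0.28 to 0.29 in pairs of different treatments. Mitochondrial rRNA took 6.03% to 8.86% of footprint reads and 0.355% to 0.368% of RNA reads. Of the 19 matched marker genes of B cells, myeloid and erythroid cells and stroma, 17 had a mean RNA value under 1 RPKM, with a list median of 0.0118 RPKM. CD79A and CD79B, parts of the B-cell receptor, were the 2 tested markers, and neither was called in any of the 3 comparisons.

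Translational efficiency, the footprint level of a gene relative to its RNA level, asks which mRNAs lose ribosomes relative to others when eIF4A is inhibited. RPKM is scaled to each library's total, so every fall or rise here is relative, and a general loss of translation would not be seen. The median log2 change over genes was -0.08 as deposited, -0.013 with median scaling and 0.001 with TMM factors. BCL11B, a zinc finger transcription factor of T-cell commitment, showed the clearest fall among T-ALL genes. Its translational efficiency fell by 1.26 on the log2 scale (SE 0.08, adjusted p = 2.7e-04). BCL11B footprints were 19.5 ± 0.071 RPKM (SD, n = 2) in DMSO and 9.61 ± 0.49 RPKM (n = 2) in silvestrol, while its RNA was 18.8 ± 0.46 RPKM (n = 3) and 22.9 ± 0.23 RPKM (n = 3). The anti-apoptotic gene BCL2 fell by 0.89 (SE 0.19, adjusted p = 0.039), and the transcription factor ETS1 fell by 0.69 (SE 0.13, adjusted p = 0.026). The cell cycle kinase CDK6 fell by 0.50 and the haematopoietic transcription factor RUNX1 fell by 0.48 (adjusted p = 0.035 and 0.027). LEF1 fell by 0.60 and TCF12 fell by 0.54, and both were named after their values were seen. Of 61 genes named in this report with a call in translational efficiency, 8 kept it with weights per assay and 6 with voom.

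The translational efficiency of MYC, the main proliferative target of NOTCH1 in T-ALL, fell by 0.63 (SE 0.11, adjusted p = 0.018). MYC footprints were 139 ± 4.2 RPKM (SD, n = 2) in DMSO and 118 ± 7.1 RPKM (n = 2) in silvestrol. MYC RNA was 77.9 ± 4.3 RPKM (n = 3) and 103 ± 7.9 RPKM (n = 3), so most of the change in the ratio came from RNA. HES1, a transcriptional repressor downstream of NOTCH, rose by 0.91 (SE 0.19, adjusted p = 0.035) from an estimated 17.5 footprint reads per library. NOTCH1 itself (log2 change -0.19, adjusted p = 0.574), MYB (-0.06), CCND3 (-0.07) and MDM2 (-0.11) were not called, and the values of MYB and CCND3 turned positive under TMM scaling (0.02 and 0.01).

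**Figure D1:**
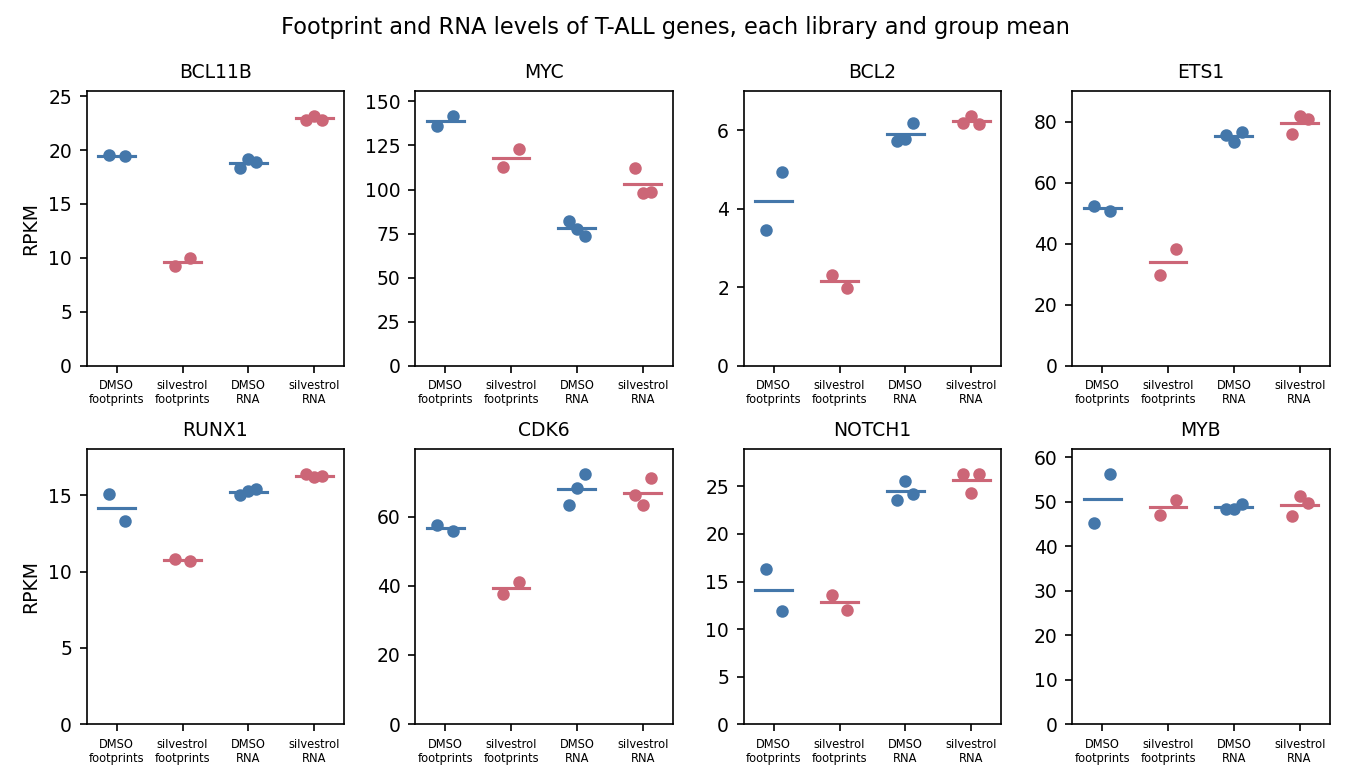
RPKM of 8 T-ALL genes in each footprint and RNA library (points) with group means (lines), DMSO in blue and silvestrol in red, on axes that start at 0. BCL11B footprints lie at 19.5 RPKM in DMSO and 9.61 RPKM in silvestrol on average, while its RNA is higher in silvestrol.

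Of 33 tested T-ALL oncogenes and transcription factors, 8 fell and 1 rose over all genes, and 10 fell and 1 rose when adjusted over the list alone. The list moved down (camera adjusted p = 0.031), and this was lost with an estimated correlation (adjusted p = 0.167 with an estimated correlation). This list was chosen with knowledge of the study, so it is not independent evidence of its direction. Of 19 genes of the NOTCH pathway and its targets, 4 fell and 1 rose, with 6 and 2 when adjusted over the list alone (camera adjusted p = 0.0979). Among them ADAM10, a protease that cleaves NOTCH receptors, fell by 0.58 and DTX1, a NOTCH target and regulator, fell by 0.54. Of 20 T-cell identity genes, 2 fell, the antigen-presenting molecule CD1B (by 0.42) and the T-cell receptor adaptor TRAT1 (by 0.41), with 4 when adjusted over the list alone (camera adjusted p = 0.296).

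Of 36 chromatin regulators, 3 fell, with 5 when adjusted over the list alone. The list moved down (camera adjusted p = 0.039), which was lost with an estimated correlation (adjusted p = 0.167 with an estimated correlation), with median scaling (0.0528), in genes with a coding sequence (0.0531) and with the correction for coding GC in those genes (0.0931). Among them the methylcytosine dioxygenase TET3 fell by 1.17 and the acetyltransferase EP300 fell by 1.02, and neither was called with weights per assay or voom. Of 26 immediate early and short-lived mRNAs, 4 fell, with 6 when adjusted over the list alone (camera adjusted p = 0.291). They included HEXIM1, an inhibitor of the elongation kinase P-TEFb (fell by 0.92), the AP-1 member JUNB (fell by 0.59) and the NF-kB inhibitor TNFAIP3 (fell by 0.48). Of 26 PI3K and mTOR genes, 1 fell, the insulin receptor substrate IRS1 (by 1.60, from an estimated 27.5 reads), with 1 when adjusted over the list alone (camera adjusted p = 0.701).

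Of 76 cytosolic ribosomal proteins, 9 fell and 4 rose, with 13 and 4 when adjusted over the list alone (camera adjusted p = 0.332). RPLP1 fell by 1.13 and RPS28 fell by 0.99, while RPL12 and RPSA each rose by 0.83. These genes have many pseudogenes and the treatment of reads that map to several places is not given, so their values are uncertain. Of 20 other TOP mRNAs, 3 fell, NPM1 (by 0.46), PABPC1 (by 0.36) and NACA (by 0.28), with 8 when adjusted over the list alone (camera adjusted p = 0.0508). Of 39 initiation factors, 1 fell, the start codon selection factor EIF1 (by 0.33), with 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.701). The drug's target EIF4A1 (log2 change -0.09, adjusted p = 0.828) and its paralog EIF4A2 (0.20) were not called. Among 23 aminoacyl-tRNA synthetases MARS1 fell by 0.34 and KARS1 rose by 0.28, with 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.701).

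Of 74 nuclear-encoded oxidative phosphorylation genes, 5 rose and 0 fell, with 5 when adjusted over the list alone (camera adjusted p = 0.0763). The list was called up with median scaling (camera adjusted p = 0.0450) and with the correction for coding GC (0.0150, and 0.433 with an estimated correlation). Both settings recentre the libraries, so their results are not separate evidence. The respiratory complex I subunits NDUFS4 (rose by 0.62) and NDUFV1 (rose by 0.40) and the ATP synthase subunits ATP5PD (rose by 0.54) and ATP5F1C (rose by 0.33) were among them. Of the 13 mitochondrially encoded mRNAs, which are translated by mitochondrial ribosomes, MT-CYB fell by 0.57, with 3 lower when adjusted over the list alone (camera adjusted p = 0.122). Of 72 mitochondrial ribosomal proteins, 2 fell, MRPL14 (by 0.37) and MRPL20 (by 0.32), with 0 when adjusted over the list alone (camera adjusted p = 0.0979). As a list they had a median of 0.00 and were called up with median scaling (median 0.06, camera adjusted p = 0.0450) and with the correction for coding GC (median 0.08, 3 higher and 0 lower, 0.0150, and 0.356 with an estimated correlation). PSMB5, a catalytic subunit, rose by 0.44 as the 1 call among 29 proteasome genes, with 0 when adjusted over the list alone (camera adjusted p = 0.460). In the apoptosis list of 22, BCL2L1 and BCL2 fell (by 0.57 and 0.89) and BAX rose by 0.42, with 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.812).

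A further 5 lists had 1 call each, all lower. They were the glucose transporter SLC2A1 (fell by 0.75) among 18 glycolysis genes, squalene epoxidase SQLE (fell by 0.78) among 21 cholesterol synthesis genes, SNRPD2 (fell by 0.45) among 37 splicing factors, HSPA4 (fell by 0.34) among 32 chaperones, and CDK6 among 33 cell cycle genes. Adjusted over the list alone the counts were 1, 2, 1, 1 and 1, and the camera adjusted p were 0.978, 0.332, 0.978, 0.701 and 0.978. Of 21 integrated stress response genes, XBP1 fell by 0.60 and PPP1R15B fell by 0.30, with 2 when adjusted over the list alone (camera adjusted p = 0.701). None of 19 snoRNA host and NMD-sensitive transcripts was called or passed when adjusted over the list alone (camera adjusted p = 0.701). Of the 25 matched replication-dependent histones 4 were tested, too few for a list test. The list median was 601 RPKM in footprints and 0.476 RPKM in RNA, and the linker histone H1-2 rose by 0.34. How the RNA was selected is not given in the sources used here, and these mRNAs lack a poly(A) tail, so a ratio to RNA is uncertain for them. Of the 25, 21 had a mean under 1 RPKM in RNA and 4 in footprints, which argues against RNA libraries that captured these mRNAs in full.

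In all, 411 genes were called lower and 134 higher of 10297 (median log2 change -0.08), and 2300 genes had an unadjusted p under 0.05. In simulation with nothing changed this fit gave 106 calls and 1718 of 10052 genes at an unadjusted p under 0.05, so most of that count needs no change in translation. Median scaling of the libraries split the calls 275 lower and 180 higher, quantile normalization 314 and 207, and TMM factors 262 and 205. A correction for coding GC, chosen after the data were seen, gave 290 and 241 in the 8767 genes with a 5' UTR. Without the correction those genes gave 355 and 100. The correction also recentred the libraries (median log2 change -0.079 before and -0.0014 after), so the more even split is not shown to come from GC. Among protein-coding genes with at least 20 estimated footprint reads the largest falls, chosen after the values were seen, included NOCT, a circadian gene of the deadenylase family (by 1.29), SHISA2 (by 1.26) and PPP1R9B (by 1.22). The largest rises included PPM1M (1.74), IFT20, an intraflagellar transport gene (1.19), the checkpoint loader RAD17 (1.14) and PAAF1, a proteasome assembly factor (1.06). The largest changes of all were in very short or non-coding genes such as MIR331, MIR4749, MIR4690 and PIGY, with an estimated 0.75 to 2.25 footprint reads per library. ACTB (-0.18), GAPDH (0.08) and TUBA1B (-0.49, adjusted p = 0.0570) were not called.

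These counts rest on 1 spread for both assays, although footprints varied several times more than RNA, and in simulation 62.5% of such calls were false. With weights per assay, 9 genes were lower and 2 higher, all among the 545 called above, and with voom on estimated reads 17 and 3. Weights per assay also gave 11 calls in simulation with nothing changed, as many as here. BCL11B was called in all 3 treatments of the spread (adjusted p = 0.0415 with weights and 0.0036 with voom), as were 3 antisense transcripts, SIAH2-AS1, ENSG00000226605 and ENSG00000236772. RPLP1, PIGY, MIR4749 and PA2G4, a growth regulator, were also called with weights (adjusted p = 0.0193, 7.1e-04, 0.0060 and 0.0415), and LEF1 and IRS1 with voom (adjusted p = 0.0170 and 0.0253). MYC, BCL2, ETS1, CDK6, RUNX1, EP300 and HEXIM1 were called in neither (adjusted p with weights 0.777, 0.476, 0.483, 0.831, 0.594, 0.304 and 0.179). Most of the other genes named above with a call, list members included, were also called in neither.

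The series title names RNA G-quadruplexes, so the 5' UTRs of genes with lower translational efficiency were compared with those of genes not called. The called genes came from the fit with 1 spread for both assays, 62.5% of whose calls were false in simulation. False calls can make a difference between the groups look smaller, so a motif that does not pass is not shown to be without a role. The 347 called genes with a 5' UTR had a longer one, with a median of 267 nt against 188 nt in 8325 genes (permutation p = 1e-05, the smallest the resamples can give, adjusted p = 1.2e-04). Their GC content was 65.9% against 65.8% (permutation adjusted p = 0.928). A run of 4 GGC or CGG repeats was present in 7.20% against 4.42% (odds ratio 1.68, Fisher's exact p = 0.0238, adjusted p = 0.0947), and a predicted G-quadruplex in 72.0% against 66.7% (odds ratio 1.29, p = 0.0414, adjusted p = 0.0994). Neither motif passed the adjustment over 12 tests. Against uncalled genes matched on 5' UTR length and GC, the odds ratios were 1.25 for the repeats (Fisher's exact p = 0.369) and 0.876 for the predicted G-quadruplex (p = 0.358). With each gene's longest annotated 5' UTR both passed, at odds ratios of 2.24 and 1.70 (adjusted p = 7.4e-04 for each). Against genes matched on the length and GC of that 5' UTR, a comparison chosen after the data were seen, the odds ratio was 1.84 for the repeats (Fisher's exact p = 0.0121, adjusted p = 0.0727) and 1.098 for the predicted G-quadruplex (p = 0.627).

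Across 8767 genes, the change in translational efficiency fell with 5' UTR length (Pearson's r = -0.1195, Spearman's rho = -0.172, permutation p = 1e-04, the smallest possible, adjusted p = 1.3e-04 over 24 relations). The relation with footprints alone was rho = -0.151 and with RNA rho = 0.130. In 4 classes of about equal size by 5' UTR length, the median log2 change in translational efficiency was 0.00 in the shortest, then -0.07, -0.10 and -0.15 in the longest. These medians hold for libraries as deposited, and their zero point moves with the scaling. The GC content of the 5' UTR gave rho = 0.018 (adjusted p = 0.102), and rho = 0.024 (permutation p = 0.0354, adjusted p = 0.0405) in the 7868 genes with at least 20 estimated footprint reads. The 95 genes called higher had a median 5' UTR of 138 nt (permutation adjusted p = 0.0947) and a shorter coding sequence, 900 nt against 1371 nt (adjusted p = 0.0021). Across genes the relation with coding length was slight, at rho = -0.052, and -0.058 in genes with at least 20 estimated footprint reads. Whether the read numbers of short genes play a part in the difference was not tested.

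**Figure D2:**
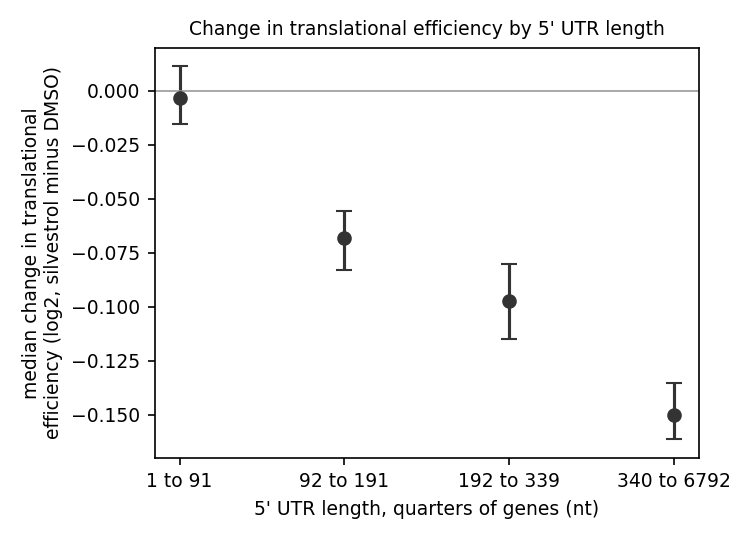
Median log2 change in translational efficiency (silvestrol minus DMSO) of genes in 4 classes of 5' UTR length in nt, with 95% bootstrap intervals over genes. With libraries as deposited, the median goes from 0.00 in the shortest class to -0.15 in the longest.

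The footprint comparison asks which genes changed in ribosome occupancy relative to other genes, whatever their RNA. Of 10297 genes, 3 were lower and 2 higher, none of them protein-coding, and 719 had an unadjusted p under 0.05 where chance gives 515. Simulation with nothing changed gave 11 calls, more than the 5 here, and 429 genes at an unadjusted p under 0.05. MIR331, MIR4749 and ENSG00000226605 were listed at 0 in both silvestrol libraries, after 18.1, 12.2 and 9.19 RPKM in DMSO, and MIR4690 was listed at 0 in DMSO and at 34.0 RPKM in silvestrol. These 4 genes had at most an estimated 2.25 footprint reads per library. The fifth, ENSG00000252690, a non-coding transcript with an estimated 494 reads, rose from 22.3 ± 2.1 RPKM (SD, n = 2) to 83.7 ± 3.4 RPKM (n = 2), a log2 change of 1.89 (SE 0.14, limma adjusted p = 0.033). None of the 22 lists passed; T-ALL genes had a median of -0.15 (camera adjusted p = 0.143, and 1 gene lower when adjusted over the list alone) and chromatin regulators -0.17 (camera adjusted p = 0.143). BCL11B (log2 change -0.98, adjusted p = 0.403), ETS1 (-0.61), CDK6 (-0.52), RUNX1 (-0.38), BCL2 (-0.81), MYC (-0.24), NOTCH1 (-0.12), MDM2 (-0.08), EIF4A1 (-0.08) and MYB (-0.05) were not called. MYB turned positive under median scaling (0.00) and TMM factors (0.03). Leaving out any 1 footprint library gave 0 calls with limma, with 510 to 772 genes at an unadjusted p under 0.05, and voom on estimated reads called 22 lower and 7 higher.

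The RNA comparison asks which transcripts changed in level within 45 minutes. MYC RNA rose by 0.40 on the log2 scale (SE 0.06, limma adjusted p = 0.045), BCL11B by 0.28 (SE 0.03, adjusted p = 0.0093) and JUNB by 0.27 (SE 0.04, adjusted p = 0.023). The zinc finger genes ZNF184 (0.32), ZNF174 (0.28) and ZNF394 (0.26) rose, as did PHF23 (0.33), KRCC1 (0.32), C6orf47 (0.30), TEX19 (0.30), the neural transcription factor POU3F2 (0.27), the mitochondrial alanine tRNA MT-TA (0.34) and the unnamed gene ENSG00000221182 (0.45). APOOL, a mitochondrial inner membrane protein, was the 1 gene that fell (by 0.33). In all 28 genes rose and 1 fell, none by more than 1 on the log2 scale, and 716 genes had an unadjusted p under 0.05 in the upward and 234 in the downward direction.

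**Figure D3:**
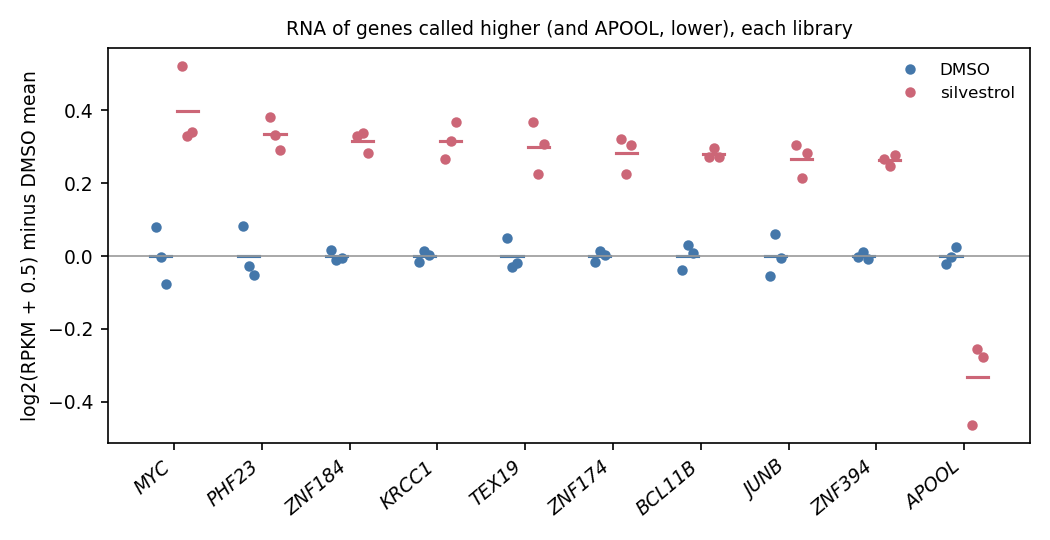
log2(RPKM + 0.5) of 10 called genes in each RNA library, minus the DMSO mean, with DMSO in blue, silvestrol in red and lines at group means. For MYC the silvestrol mean lies 0.40 above DMSO and for APOOL 0.33 below.

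Among the lists, T-ALL genes (33 tested, 2 higher, 3 when adjusted over the list alone) moved up in RNA (camera adjusted p = 0.0063), which was lost with an estimated correlation (adjusted p = 0.350). The T-ALL list is not independent evidence here either. Up as well were the 13 mitochondrially encoded mRNAs (median 0.11, 0 called, 7 when adjusted over the list alone, camera adjusted p = 1.1e-04, 0.535 with an estimated correlation), 26 immediate early and short-lived mRNAs (median 0.05, 2 called, 5 when adjusted over the list alone, adjusted p = 0.0109, 0.706 with an estimated correlation), 19 snoRNA host and NMD-sensitive transcripts (median 0.04, 0 called, 2 when adjusted over the list alone, adjusted p = 0.0109, 0.535 with an estimated correlation) and 76 ribosomal proteins (median 0.02, 0 called, 1 when adjusted over the list alone, adjusted p = 0.0244, 0.9002 with an estimated correlation). The 33 cell cycle genes (median -0.02, adjusted p = 0.0109, 0.535 with an estimated correlation) and 21 cholesterol synthesis genes (median -0.03, adjusted p = 0.0116, 0.350 with an estimated correlation) moved down, with 0 called and 0 when adjusted over the list alone. After the correction for coding GC, 2 cell cycle genes were lower and 1 higher, with 10 and 1 when adjusted over the list alone. Members not called included MT-ND4L (0.12) and MT-ATP8 (0.12), which were 0.00 and -0.02 under quantile normalization, SNHG3 (0.12), SNHG12 (0.12), RPS27 (0.28, adjusted p = 0.051), RPS10 (0.10), BUB1, a spindle checkpoint kinase (-0.10), and E2F2 (0.12). Also not called were EP300 (0.18, adjusted p = 0.103), the RNA helicase DDX3X (-0.22, adjusted p = 0.228), SQLE (-0.07), INSIG1 (-0.05), RUNX1 (0.09), ETS1 (0.08), BCL2 (0.08), NOTCH1 (0.07), CDK6 (-0.02), MYB (0.01), EIF4A1 (0.01), ACTB (-0.06) and GAPDH (-0.01). After the correction for coding GC, chosen after the data were seen, 7 of these were called, RPS27, EP300, E2F2 and RPS10 higher and DDX3X, BUB1 and ACTB lower (limma adjusted p = 0.0027, 0.0215, 0.0317, 0.0339, 0.0178, 0.0235 and 0.0412). No list passed with an estimated correlation. The ribosomal protein list was also lost with median scaling (camera adjusted p = 0.0708), the short-lived list with the correction for coding GC (0.0698), and the snoRNA host list with that correction (0.0698) and in genes with a coding sequence (0.0549). The number of RNA calls depended on the genes and libraries used. It was 0 with limma without a filter on low genes (1394 of 17428 genes at an unadjusted p under 0.05), 4 lower and 78 higher in genes with an annotated coding sequence, and 38 lower and 170 higher in those genes with the correction for coding GC. Without DMSO RNA library 1 or 3 it was 0 (743 and 846 genes at an unadjusted p under 0.05), without DMSO RNA library 2 it was 5 higher, and without silvestrol RNA library 3 it was 1 higher.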

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

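The alternatives with voom, at least 20 estimated reads, protein-coding genes, genes with a coding sequence, the correction for coding GC and the background matched on the longest 5' UTR were chosen after the data were seen. Counts below are genes called lower and higher. The 411 and 134 genes in translational efficiency became 619 and 272 with no filter, 296 and 79 at a mean RPKM of at least 5, 275 and 180 with median scaling, 314 and 207 with quantile normalization, 262 and 205 with TMM factors, 290 and 241 with the correction for coding GC, and 809 and 285 at an adjusted p under 0.10. With a replicate block they were 42 and 17, with weights per assay 9 and 2, with voom 17 and 3, and with ratios of footprint to RNA libraries of the same number 0 and 0 in limma (673 genes at an unadjusted p under 0.05), although the labels do not say that numbers pair libraries. Pseudocounts of 0.1 and 1, eBayes without trend or robust, at least 20 estimated reads, protein-coding genes and genes with a coding sequence gave 355 to 416 lower and 95 to 155 higher. The correction for coding GC, which also recentred the libraries, gave 290 and 241 in genes with a coding sequence, against 355 and 100 in these genes without it. Leaving out 1 of the 6 RNA libraries gave 64 to 88 lower and 27 to 33 higher. Leaving out 1 of the 4 footprint libraries gave 1153 to 1755 lower and 574 to 895 higher. The lone footprint library left in a group is then assumed to vary like the other groups, so the spread rests more on RNA.

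Footprint calls, 3 and 2, were 0 and 2 with a pseudocount of 0.1 and at a mean RPKM of at least 5, 1 and 1 with no filter, and 3 and 5 with quantile normalization and with TMM factors. They were 0 and 1 in eBayes without trend or robust, with a replicate block and at least 20 estimated reads, 4 and 5 at an adjusted p under 0.10, and 22 and 7 with voom. With all 10 libraries in 1 fit they were 1157 and 468, where RNA lowers the estimated spread. They were 0 and 0 in limma in protein-coding genes, genes with a coding sequence and with the correction for coding GC (739, 723 and 695 genes at an unadjusted p under 0.05), and 0 to 0 when any 1 of the 4 footprint libraries was left out. RNA calls, 1 and 28, were 0 and 0 with no filter and with all 10 libraries in 1 fit (1394 and 45 genes at an unadjusted p under 0.05 in limma), 2 and 36 at a mean RPKM of at least 5, 2 and 19 with median scaling, 0 and 23 with quantile normalization, and 2 and 25 with TMM factors. They were 0 and 4 in eBayes without trend or robust, 4 and 67 at an adjusted p under 0.10, 8 and 49 with a replicate block, and 1 and 2 with only RNA libraries numbered 1 and 2. They were 3 and 43 at 20 estimated reads, 4 and 69 with voom, 4 and 64 in protein-coding genes, 4 and 78 in genes with a coding sequence, and 38 and 170 with the correction for coding GC. Leaving out 1 RNA library gave 0 to 5 lower and 0 to 30 higher, lowest without DMSO libraries 1 and 3 (0 each), silvestrol library 3 (1) and DMSO library 2 (5). Lists called down and up in translational efficiency, 2 and 0, were 0 and 0 with an estimated correlation and 1 (T-ALL genes) and 2 (oxidative phosphorylation and mitochondrial ribosomal proteins) with median scaling and with the correction for coding GC, and 1 and 0 in genes with a coding sequence. Lists in RNA, 2 and 5, were 0 and 0 with an estimated correlation and 2 and 4 with median scaling. They were 2 and 3 in genes with a coding sequence and an annotated 5' UTR. With the correction for coding GC the same genes gave 2 and 2. In this set the mitochondrially encoded list is not tested, and the snoRNA host list has 8 genes.

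For genes called lower, the difference in median 5' UTR length was 79 nt and 84.5 to 86 nt in 2 alternatives. The difference in 5' UTR GC was -0.146 percentage points in the 300 genes with the lowest statistics. With the longest 5' UTR the odds ratio was 2.24 for repeats and 1.70 for the predicted G-quadruplex, and 1.84 and 1.098 against genes matched on that 5' UTR. With the main 5' UTR the odds ratio of the predicted G-quadruplex was 1.29, and 0.876 against its matched background. Over named genes and settings, 1331 of 1888 values kept direction and side of the threshold in translational efficiency, 256 of 314 in footprints and 687 of 824 in RNA. BCL11B lost its call in translational efficiency in 1 setting and MYC in 7. Values that changed sign, none of them called, were in translational efficiency MYB (median scaling 0.0021, TMM 0.022, coding GC 0.0127) and CCND3 (TMM 0.0131, coding GC 0.0226), and in footprints MYB (0.0027, 0.0282 and 0.0257) and EIF4A1 (coding GC 8.6e-04). In RNA they were MT-ATP8 (-0.0194) with quantile normalization, where MT-ND4L went to 0, and EIF4A1 (-0.0050) with median scaling. Without 1 library, translational efficiency ran across 0 for NOTCH1 (-0.405 to 0.0327), MYB (-0.22 to 0.10), CCND3 (-0.149 to 0.0057), MDM2 (-0.49 to 0.27), CD79B (-0.77 to 0.21) and EIF4A1 (-0.36 to 0.18). Footprints did for NOTCH1 (-0.34 to 0.10), MYB (-0.21 to 0.11), MDM2 (-0.46 to 0.30), CD79B (-0.87 to 0.10) and EIF4A1 (-0.36 to 0.19), and RNA for MYB (-0.0148 to 0.0494), EIF4A1 (-2.0e-04 to 0.0247) and CDK6 (-0.0703 to 0.0249). Lists that changed direction had adjusted p of 0.808 (cell cycle in translational efficiency, median scaling), 0.840 (the same, coding GC), 0.899 and 0.817 (splicing factors in footprints, median scaling and coding GC), 0.981 (cell cycle and snoRNA hosts in translational efficiency, genes with a coding sequence), 0.918 and 0.985 (apoptosis and splicing factors in footprints, the same genes), 0.876 (apoptosis and glycolysis in footprints, coding GC) and 0.998 (mitochondrial ribosomal proteins in RNA, coding GC). Except where a sentence names fewer genes, fewer libraries or the spread, the cause was not tested. At the estimated 1.66 to 2.38 M reads per footprint library and 2 libraries per treatment, simulation recovered 32.8% of 2-fold footprint changes. Depth and number of libraries were not varied, so their parts in this were not tested.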

Other observations

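The tests of low footprint depth, of coding GC and length, of RNA level and of 1 footprint library were chosen only after the result was seen, as were the correction for coding GC, voom, the background matched on the longest 5' UTR and the search for zinc finger genes.

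The 545 calls in translational efficiency rest on a spread that RNA, with the lower variation, makes smaller for footprints. Of these genes 2.02% were called with weights per assay, BCL11B among them, so counting noise may make up most of the list, and simulation with nothing changed gave 106 calls, or 11 with weights, as many as were called. Of the called genes 21.3% had under 20 estimated footprint reads per library, against 18.5% of those tested. The small share among tested genes nearly fixed this outcome in advance, so the test cannot decide on low depth. Of 60 splits of the libraries, 5 called at least as many genes, with 570 as the highest other, so chance cannot be excluded. All splits that kept the real footprint groups called 408 to 570 and the others 101 to 176, so the calls follow the footprint groups, which treatment shares with any unrecorded batch.

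Genes with longer 5' UTRs had lower translational efficiency in silvestrol, at rho = -0.172. It stayed at rho = -0.177 with coding GC and length removed, -0.151 in footprints alone, -0.142 at its nearest to 0 without 1 footprint library (DMSO library 2), and -0.117 with the share of exon length in the 5' UTR removed, values that argue against each of these as the whole cause. The 2 other groupings of the 4 footprint libraries gave 0.024 and 0.010, too few groupings to exclude chance. The predicted G-quadruplexes in the longest 5' UTRs of called genes had an odds ratio of 1.70, and 1.098 against genes matched on length and GC (Fisher's exact p = 0.627), so 5' UTR length and GC may account for that excess, though not shown for the repeats (1.84, adjusted p = 0.0727). A dependence of long 5' UTRs on eIF4A is a candidate explanation of the length relation that stays open beside an unrecorded difference between the footprint groups.

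RNA calls were 29 in the real groups and at most 0 in the other 9 splits, and 10 splits are too few to judge chance. Of the 27 called genes with a coding sequence, 100% were called after the correction for coding GC. In the same set of tested genes the correction raised the number of RNA calls from 82 to 208. Keeping these calls was thus likely in advance, and it does not decide on bias by coding GC. Across genes the RNA change had Spearman's rho = 0.060 with coding GC. RNA libraries of the same treatment differed in their relation to coding GC, with Spearman's rho from -0.470 to 0.499 in DMSO and from -0.584 to 0.491 in silvestrol. The GC of 5' UTRs and the length of genes were not corrected. Slower decay of short-lived mRNAs while translation is inhibited could not be decided, as camera gave p = 0.404 with an estimated correlation and the list's median was still above 0. A hypothesis formed after the called genes were seen is that RNA of zinc finger genes, symbols starting with ZNF, rose together. After the correction, 39 of 170 higher genes were such genes, 22.9% against 2.86% of the others (odds ratio 10.1), and without the correction 4 of 28 (odds ratio 5.48), values from the libraries that prompted the idea and so no separate evidence for it. The odds ratio pooled over strata of coding GC and length was 10.4. These calls were already corrected for coding GC, so the strata bear mainly on coding length, in 5 classes, and argue against it as the whole cause. The median RNA change of the ZNF genes was 0.07, and the largest size in the other 9 splits was 0.0485. That bound was set in advance, and 10 splits are too few to rest on it. A difference between RNA libraries that does not follow treatment may remain and cannot be told apart.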
